A study of Homo sapiens with 5 samples.

How the data were processed

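Total RNA of RS4;11 cells was measured on 5 Affymetrix whole-transcript arrays, 2 of cells with the solvent DMSO and 3 of cells with 10 uM SB216763 for 20 h. Groups and replicate numbers were taken from the sample titles. The values are the log2 expression values that the authors deposited as 1 table of all arrays; that they are log2 follows from their range. Per the submitters' processing notes they were made with Affymetrix Expression Console. Its version, the summarisation method and the genome build are not given in the sources used here, so no coordinates are printed. Values lay between 1.95 and 14.84 on the log2 scale, and the array medians between 6.77 and 6.84, so no further normalization was applied. No array files before summarisation were used here, and no pair of arrays held identical values at more than 2.33% of probes.

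Probes were named through the platform annotation. Of 33297 probes, 19460 had exactly 1 gene symbol, 1754 had several and 12083 were unnamed here. Probes with several or no symbols stayed out of the main test and were tested only as an alternative. Symbols were checked through the Entrez identifier against a RefSeq gene table of assembly GRCh38.p14, which held the identifier of 19429 of the probes with 1 symbol, and 0 symbols were updated. For the 769 genes with more than 1 probe, the probe with the highest mean over all 5 arrays was used, which left 18417 genes. Among 147 called genes with several probes, 2 had another probe with an unadjusted p under 0.05 going the other way. The background of each array was the 95th percentile of 341 olfactory receptor genes, 5.98 to 6.19 on the log2 scale. By it 12071 genes were above background on all 5 arrays, as were 2201 of the 2418 called genes, and 82 called genes were above it on no array. Where a gene was above background on no array of 1 group, the fold is a lower bound, the brighter group's mean against the mean of the higher of background and the gene's own value on each array of the other; where this held for both groups, or the bound was under 1, no fold is given. No probe's level was set against another's except for this background.

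The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust settings), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The prior had 4.62 degrees of freedom and the moderated test 7.62. Standard errors and 95% intervals are those of the moderated fit. The 27 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry beside it. A list needed at least 5 measured members. Tables and figures were made with pandas 2.3.3 and matplotlib 3.10.9.

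Groups, tests, gene lists, the naming rule and the alternatives were fixed before the data were examined. The named genes were the 10 with the largest increase and the 10 with the largest decrease among genes past the threshold whose groups did not overlap, and always GSK3A, GSK3B, CTNNB1, AXIN2, LEF1, MEIS1, HOXA9, HOXA10, CDKN1B, MYC and FLT3. For each list the rule added up to 4 measured members with the smallest p. Where a count of members was 5 or fewer, genes outside the rule were named too, after their values were seen. List genes without a probe of their own were not analysed here.

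The alternatives were a filter on dim genes, quantile normalization on top, centring each array on its median, the mean of a gene's probes, a variance trend with robust settings, no moderation, array weights, the replicate number as a block, each array left out in turn, and all probes tested singly. Leaving out a control array leaves 1 control array, which is then assumed to vary like the SB216763 arrays. The procedure was tested on simulated data, in 10 simulations of the SB216763 against control comparison on 18417 genes. Each had 200 changed genes and, beside them, a shifted list, that of DNA replication. Of 1.5-fold and 2-fold changes, 93.1% and 99.9% were recovered, and 7.37% of the calls outside the shifted list were unchanged genes. Noise was drawn from the moderated variances, shuffled over genes. These vary less than unmoderated ones, so recovery in the real data may be lower. The shifted list was called in 10 of the 10 simulations, and 1 unshifted list was called over all of them. Genes were simulated independently of one another, so these counts do not show how camera behaves where members are correlated.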

Results

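RNA of the human leukemia line RS4;11, established from an acute leukemia with a rearranged MLL gene, was measured on 5 whole-transcript arrays. The line is usually described as a B cell precursor line; lineage genes on these arrays are given with their lists, and the identity of the cells was not tested here. Cells on 2 arrays had received the solvent DMSO and cells on 3 arrays had received SB216763, a small-molecule inhibitor of the kinase GSK-3, at 10 uM for 20 h. The 5 arrays each held 33297 probes, and their median log2 values lay between 6.77 and 6.84. Across probes, the control arrays correlated with a Pearson r of 0.994, the SB216763 arrays among themselves with 0.992 to 0.996, and arrays of different groups with 0.989 to 0.991. The number of arrays limits the precision, and nothing in the labels says that they came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. All differences below are SB216763 minus control on the log2 scale, with n = 2 control and n = 3 SB216763 arrays.

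The comparison asks which transcripts differ after 20 h of GSK-3 inhibition in an MLL leukemia line. ARRDC3, an arrestin-domain protein, rose from 5.51 ± 0.05 (SD, n = 2) to 8.26 ± 0.16 (SD, n = 3), at least 4.23-fold, as its control level was not above background. SLC7A11, the cystine transporter subunit, rose at least 4.29-fold from a control level not above background. ALOX12, a lipoxygenase of arachidonic acid metabolism, showed the largest fitted decrease of the genes called by limma, 5.39-fold, with a log2 difference of -2.43 (SE 0.08). MYC, the growth-promoting transcription factor, fell 2.08-fold, with a log2 difference of -1.05 (SE 0.08). Genes of DNA replication and cholesterol synthesis fell as groups, and lysosomal genes rose, by camera with a preset correlation. For each of these 3 lists the adjusted p was 0.415 with an estimated correlation.

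Of 18417 genes tested with limma, 1328 were higher and 1090 lower with SB216763 after Benjamini-Hochberg adjustment, 13.1% of the genes, and 4880 had an unadjusted p under 0.05. A change of at least 2-fold was found for 74 higher and 53 lower genes. The groups did not overlap for 7629 genes, 41.4% of those tested where chance gives 20%, and for all 2418 called genes. These calls rest on both control arrays. Without control replicate 1 limma called 1 gene, ALOX12 (adjusted p = 0.0488), with 3603 genes at an unadjusted p under 0.05, and without control replicate 2 it called 0 genes, with 3960 at that unadjusted level. The count was 993 without SB216763 replicate 1 and 1606 without SB216763 replicate 3, and an ordinary linear model without moderation called 251 genes.

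The 10 largest increases and decreases were ranked by the fitted difference, also where 1 group was not above background. Beside ARRDC3 and SLC7A11, the increases included DNASE2, the lysosomal acid nuclease, at 1.60 (SE 0.09), and SAMD9L, an interferon-induced gene. They also included NAIP, an inflammasome receptor, at 1.66 (SE 0.09), the lipid flippase ATP10D at 1.62 (SE 0.13), the adaptor proteins FYB1 at 1.56 (SE 0.12) and DAPP1, LOC441081 at 1.93 (SE 0.07) and TPTE2. SAMD9L, DAPP1 and TPTE2 were not above background on the control arrays, and their increases were at least 1.60-fold, 2.19-fold and 1.66-fold. NAIP and TPTE2 have near-identical copies elsewhere, so which copy was measured is uncertain, and LOC441081 was named by 5 probes. The largest decreases after ALOX12 were in ETV5, a transcription factor induced by ERK signalling, at least 2.46-fold lower, as it was not above background with SB216763, and in the sterol genes DHCR7 at -1.80 (SE 0.12) and INSIG1 at -1.72 (SE 0.09). DUSP6, the phosphatase that switches off ERK, fell by 1.61 (SE 0.08). ITGB5, an integrin subunit, and SYT2, a synaptotagmin, both differed by -1.46 (SE 0.08 and 0.10), and the pseudogene ANKRD18DP by -1.70 (SE 0.15). The small RNA genes MIR221 and SNORD14E differed by -1.45 (SE 0.09) and -1.43 (SE 0.17). All 20 genes had adjusted p-values from limma between 6.59e-05 and 0.00552, and of the 20 only ALOX12 kept its call without control replicate 1, and none without control replicate 2.

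**Figure D1:**
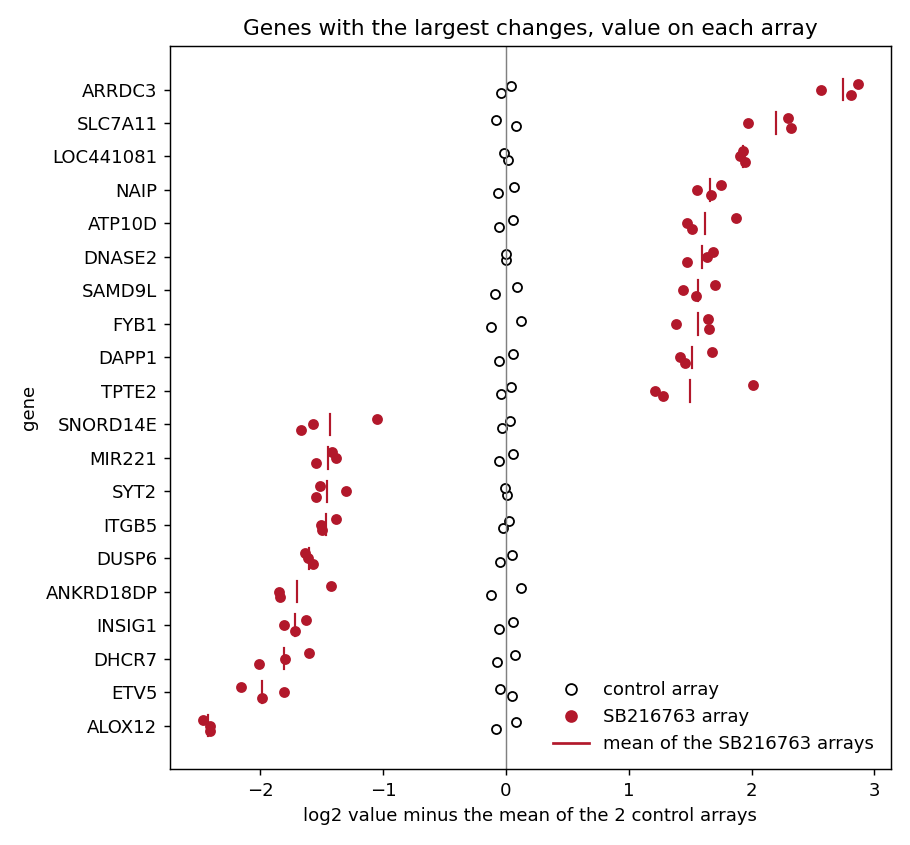
Log2 value of each array minus the mean of the 2 control arrays (horizontal axis) for the 10 genes with the largest increases and the 10 with the largest decreases (vertical axis). Open points are control arrays, filled points SB216763 arrays and vertical lines the mean of the SB216763 arrays; for ALOX12 that mean lies at -2.43, and in each gene the groups are apart. ARRDC3, SLC7A11, SAMD9L, DAPP1 and TPTE2 were not above background on the control arrays, nor ETV5 on the SB216763 arrays.

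Of the inhibitor's targets, GSK3B transcript was slightly higher, at 0.34 (SE 0.09, adjusted p = 0.0403 by limma), with an adjusted p of 0.0544 when each array was centred on its median. GSK3A differed by 0.09 (SE 0.07, adjusted p = 0.540). Inhibition of the kinase need not alter these transcripts. CTNNB1, which encodes beta-catenin, the protein that GSK-3 marks for degradation, differed by -0.28 (SE 0.09, adjusted p = 0.0918), and it passed in 4 of the other settings, with adjusted p from 0.0280 to 0.0392. The Wnt target AXIN2 differed by -0.00 (SE 0.08, adjusted p = 0.984), with a 95% interval of -0.20 to 0.19. LEF1 was below background on all 5 arrays, so its difference of -0.06 (SE 0.11) carries little information. Of the genes tied to MLL leukemia, MEIS1 differed by -0.01 (SE 0.09, adjusted p = 0.979) and the receptor gene FLT3 by -0.11 (SE 0.10, adjusted p = 0.557); HOXA9 and HOXA10 were not analysed here. CDKN1B, which encodes the cell cycle inhibitor p27, fell by 0.51 (SE 0.10, adjusted p = 0.0148). The calls of GSK3B, CDKN1B and MYC were lost without control replicate 1 and without control replicate 2.

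Of the 34 measured genes of the G1/S transition and DNA replication, 31 fell, 1 rose and 2 did not pass, and the list's median was -0.76. MCM5 and MCM7, subunits of the replicative helicase, fell by 1.03 (SE 0.07) and 1.11 (SE 0.09), CDC45, its cofactor, by 1.25 (SE 0.09), and CHAF1B, of the chromatin assembly factor, by 0.94 (SE 0.07). CDT1, the licensing factor, named after its value was seen, rose by 0.32 (SE 0.08, adjusted p = 0.0326 by limma). There were 33 lower and 1 higher adjusted over the list alone. The list was lower by camera with the preset correlation (adjusted p = 4.89e-26), with adjusted p = 0.415 with an estimated correlation. Leaving out either control array ended every single-gene call in the list (31 members lower at an unadjusted p under 0.05 in each case), while the list's median stayed between -0.79 and -0.65 whichever array was left out.

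Of 34 measured genes of G2/M and mitosis, 15 fell, among them PTTG1, the securin, by 0.66 (SE 0.08), the spindle checkpoint kinases BUB1B by 0.70 (SE 0.08) and BUB1 by 0.59 (SE 0.08), and the midzone protein PRC1 by 0.53 (SE 0.08). The other 19 did not pass, the median was -0.33, and adjusted over the list alone 25 fell and 1 rose. Camera gave adjusted p = 3.39e-11 with the preset correlation and adjusted p = 0.415 with an estimated correlation. The number of members that fell was 5 without SB216763 replicate 1. It was 0 by limma without either control array, with 22 lower at an unadjusted p under 0.05 without control replicate 1 and 11 without control replicate 2.

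Of 28 measured genes of MYC and ribosome biogenesis, 12 fell, 1 rose and 15 did not pass, with a median of -0.36. The fallen genes included RRP12 and NOP16, factors of ribosome assembly, by 0.73 (SE 0.08) and 0.61 (SE 0.07), the mitochondrial chaperonin HSPE1 by 0.73 (SE 0.11) and DKC1, the pseudouridine synthase of H/ACA particles, by 0.60 (SE 0.09). The gene that rose, IMPDH2 of guanine nucleotide synthesis, was named after its value was seen and differed by 0.38 (SE 0.09). Adjusted over the list alone 19 fell and 1 rose, and camera gave adjusted p = 2.86e-09 with the preset correlation and adjusted p = 0.415 with an estimated correlation. Of 14 heat shock genes, 7 fell, with a median of -0.40, among them HSPA4L by 0.98 (SE 0.10), the HSP90 co-chaperone FKBP4 by 0.66 (SE 0.08), HSPH1 by 0.59 (SE 0.09) and HSP90AA1 by 0.43 (SE 0.09). Adjusted over the list alone 12 heat shock genes fell; camera gave adjusted p = 1.35e-07, and adjusted p = 0.415 with an estimated correlation. Without either control array limma called 0 members of both lists, with 19 and 13 MYC list genes and 10 and 8 heat shock genes lower at an unadjusted p under 0.05; without SB216763 replicate 1, 8 MYC list genes and 4 heat shock genes fell.

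Of 20 measured genes of cholesterol synthesis and its regulator SREBP2, 13 fell and 7 did not pass, with a median of -0.46. INSIG1, which retains SREBP in the endoplasmic reticulum, fell from 10.82 ± 0.08 (SD, n = 2) to 9.10 ± 0.09 (SD, n = 3). DHCR7, of the last step of the pathway, fell by 1.80 (SE 0.12), the squalene epoxidase SQLE by 1.16 (SE 0.09) and ACAT2 by 0.78 (SE 0.09). Adjusted over the list alone 15 fell and 1 rose; camera gave adjusted p = 1.48e-09, and adjusted p = 0.415 with an estimated correlation. Of 15 genes of fatty acid synthesis, 6 fell, 3 rose and 6 did not pass, and adjusted over the list alone 6 fell and 4 rose. The desaturases FADS2 and SCD fell by 0.78 (SE 0.09) and 0.99 (SE 0.12), and FASN and ACACA, which make palmitate, by 0.62 (SE 0.08) and 0.45 (SE 0.08), while ACSS2, ME1 and ELOVL5, named after their values were seen, were the 3 higher, ME1 being above background on no array. This second list was not called by camera (adjusted p = 0.0732), which gave 0.0496 without SB216763 replicate 3 and 0.0333 among the brighter genes. Without either control array limma called 0 members of both lists, with 12 cholesterol genes lower at an unadjusted p under 0.05 in each case, and without SB216763 replicate 1 the cholesterol genes that fell numbered 8.

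Of 31 measured genes of the lysosome and its regulator TFEB, 13 rose and 18 did not pass, with a median of 0.31. The sialidase NEU1 rose 2.15-fold, a log2 difference of 1.10 (SE 0.09), ATP6V1A of the proton pump by 0.79 (SE 0.09), the protease CTSB by 0.65 (SE 0.08) and the membrane protein LAMP1 by 0.74 (SE 0.09). The number that rose was 22 adjusted over the list alone. Camera gave adjusted p = 1.48e-09 with the preset correlation and adjusted p = 0.415 with an estimated correlation. Without either control array limma called 0 members, with 15 and 20 higher at an unadjusted p under 0.05, and 8 rose without SB216763 replicate 1.

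Of 28 measured myeloid genes, 7 rose and 21 did not pass, with a median of 0.08, which ran from 0.014 without SB216763 replicate 2, over 0.037 without control replicate 1, to 0.14 without control replicate 2, and was 0.016 among the brighter genes. It was 0.038 after quantile normalization, 0.042 with each array centred and 0.047 with array weights. The macrophage glycoprotein CD68 rose by 1.00 (SE 0.08), the receptor CSF3R by 1.23 (SE 0.11), the signalling adaptor TYROBP by 0.70 (SE 0.08) and lysozyme, LYZ, by 0.78 (SE 0.09). MNDA and CD86, named after their values were seen, were also called higher but above background on no array. Those that rose numbered 9, with 1 lower, adjusted over the list alone. Camera gave adjusted p = 0.0319, and adjusted p = 0.553 with an estimated correlation; it was 0.0978 without control replicate 2, 0.145 without SB216763 replicate 2, 0.291 among the brighter genes and 0.0751 with array weights. Of 30 genes of B cell precursors, CD37 and TCF4 rose, by 0.89 and 0.40, BLNK and BCL6 were called higher, and CD38 and IRF4 fell, by 0.74 and 0.42 (list adjusted p = 0.501), where TCF4 and IRF4 were named after their values were seen. BCL6 was above background on no array, and BLNK not on the control arrays, which makes its rise at least 1.53-fold. The counts of 4 higher and 2 lower were 5 and 2 adjusted over the list alone. Of 22 T and NK cell genes, NKG7 and CD4 rose, by 0.88 and 0.69, over all genes and adjusted over the list alone (list adjusted p = 0.977). Of 17 erythroid and megakaryocyte genes limma called 0, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.501, fry 0.568). On both control arrays, 24 of the 28 myeloid genes, 15 of the 30 B cell precursor genes, 11 of the 22 T and NK cell genes and 9 of the 17 erythroid genes were above background. Without either control array limma called 0 members of these lists, with 8 and 7 myeloid genes higher at an unadjusted p under 0.05.

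Of 23 measured genes of cytokine and MAPK signalling feedback, 7 fell, 1 rose and 15 did not pass, with a median of -0.22, or -0.14 both without control replicate 2 and without SB216763 replicate 3. Beside DUSP6 and ETV5, ETV4 fell by 1.42 (SE 0.11) and the kinase PIM2 by 1.12 (SE 0.09), while BCL6, named here after its value was seen, was the 1 called higher but was above background on no array. Adjusted over the list alone 7 fell and 2 rose; camera gave adjusted p = 0.00180, and adjusted p = 0.415 with an estimated correlation. Of 31 genes of glycolysis and hypoxia, 6 fell, among them the glucose transporter SLC2A1 by 0.92 (SE 0.08), NDRG1 by 0.84 (SE 0.08), PFKP by 0.66 (SE 0.08) and PDK1 by 0.69 (SE 0.10), and VEGFA, outside the naming rule for this list, rose by 0.62 (SE 0.10). Adjusted over the list alone 8 fell and 1 rose; camera gave adjusted p = 0.0297, and adjusted p = 0.415 with an estimated correlation. Of 22 genes of endoplasmic reticulum chaperones and XBP1, HERPUD1, SDF2L1, XBP1 and HYOU1 fell by 0.98, 0.87, 0.72 and 0.32, and CREB3L2, named after its value was seen, rose by 0.31; adjusted over the list alone 4 fell and 1 rose. Camera gave adjusted p = 0.0313 for this list, and adjusted p = 0.415 with an estimated correlation. The last 2 lists were not called without control replicate 2 (0.0519 and 0.0789) or without SB216763 replicate 2 (0.121 for both), nor with array weights (0.0751 for both), nor, for the chaperone list, among the brighter genes (0.0744). In the 3 lists limma called 0 members without either control array, with 9 and 8 feedback genes lower at an unadjusted p under 0.05.

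The Wnt and GSK-3 lists did not pass camera. Of 23 measured Wnt target genes, MYC, CD44 and KREMEN1 fell, by 1.05, 0.46 and 0.51, PRICKLE1 rose, by 0.47, and RNF43 was called higher. The list was lower by camera, with a median of -0.07 and a mean of -0.14 (list adjusted p = 0.0530). Its median was -0.34 among the brighter genes (camera adjusted p = 0.117) and -0.11 without control replicate 2. Camera gave the list, again lower, adjusted p = 0.0187 without SB216763 replicate 2 and 0.0330 with array weights. KREMEN1 was named after its value was seen, RNF43 was not above background on the control arrays, and adjusted over the list alone 4 Wnt targets fell and 2 rose. Only 14 of the 23 Wnt targets were above background on all 5 arrays. Of 30 components of GSK-3 and Wnt signalling, TLE4 and LRP5 fell, by 0.60 and 0.35, and GSK3B rose, by 0.34, over all genes and adjusted over the list alone (list adjusted p = 0.737). Of 7 measured genes of the HOXA cluster and its TALE partners PKNOX1 fell, by 0.45 (list adjusted p = 0.737). Of 26 MLL fusion target genes BCL2 and MEF2C fell, by 0.39 and 0.36 (list adjusted p = 0.977). The counts of these 2 lists were equal when adjusted over the list alone. Of 24 CREB and cAMP responsive genes, FOS, EGR1 and CITED2 fell, by 1.28, 0.94 and 0.63, and CREBBP rose, by 0.45, also when adjusted over the list alone (list adjusted p = 0.559; median 0.01, mean -0.11, lower by camera). Of 16 CDK inhibitors and quiescence genes CDKN1B fell, and TOB1 and CCNG2 rose, by 0.51 and 0.40, also when adjusted over the list alone (list adjusted p = 0.575). Without either control array limma called 0 members of these lists.

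The lists of ATF4, NRF2, AHR, p53, BCL2 family, interferon and NF-kB genes did not pass camera, and all but the BCL2 family had members called both ways. Of 33 genes of ATF4 and the amino acid response, 6 rose and 3 fell, or 8 and 4 adjusted over the list alone, among them SLC7A11, higher, and the transporters SLC7A5 and SLC7A1, at -1.24 and -0.53, with PSAT1 at -0.67 (list adjusted p = 0.868). Of 17 NRF2 target genes, 4 rose and 4 fell, or 6 and 4 adjusted over the list alone, with ABCC2 higher, AKR1C1 at -1.02, GSR at 0.48 and TXNRD1 at -0.49 (list adjusted p = 0.977; lower by camera, higher by fry). ABCC2 was not above background on the control arrays, which makes its rise at least 1.77-fold, and AKR1C1 was above it on 3 of the 5 arrays. The rest of those 8 were FTL, SQSTM1, PRDX1 and GCLM, named after their values were seen. Of 9 AHR target genes ALDH1A3, CYP1A1 and TIPARP fell, by 1.36, 0.59 and 0.57, and CYP1B1 rose, by 0.34, or 3 and 2 adjusted over the list alone (list adjusted p = 0.180). Of 26 p53 target genes ZMAT3, CCNG1, POLH and SESN1 rose, by 0.87, 0.56, 0.47 and 0.36, and PLK3 fell, by 0.35, or 9 and 4 adjusted over the list alone, SESN1 being named after its value was seen (list adjusted p = 0.115). Of 17 BCL2 family genes BCL2L11, PMAIP1, BCL2 and BID fell, by 0.50, 0.50, 0.39 and 0.30, or 5 with 1 higher adjusted over the list alone (list adjusted p = 0.0646, and 0.0307 without control replicate 2). Of 30 interferon responsive genes, 6 rose and 2 fell, or 8 and 2 adjusted over the list alone, with XAF1 at 1.15, and SAMD9L, RSAD2 and IFIH1 higher (list adjusted p = 0.0732, and 0.0379 without SB216763 replicate 1). SAMD9L, RSAD2 and IFIH1 were not above background on the control arrays, and the rises of RSAD2 and IFIH1 were at least 1.24-fold and 1.72-fold. The 2 that fell, IFITM1 and BST2, were named after their values were seen. Of 26 NF-kB and inflammatory genes TNF and TNFAIP3 fell, by 1.30 and 0.63, CCL2 was called lower, and 5 rose, including NFKBIA by 0.48, or 4 and 6 adjusted over the list alone (list adjusted p = 0.847; median 0.03, mean -0.01, higher by camera). CCL2 was above background on no array. The other 4, named after their values were seen, were REL, CCL5, BCL3 and NFKB2. Without either control array limma called 0 members of these lists.

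Over the 27 lists, camera with the preset correlation called 8 lower and 2 higher. With an estimated correlation it called 0 of 27, with 2 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.415. The lists that share this 0.415 had unadjusted p from 0.0272 for DNA replication to 0.231 for the chaperones of the endoplasmic reticulum. The test fry, which asks whether a list's genes moved on balance and not whether they moved more than other genes, called 15.

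**Figure D2:**
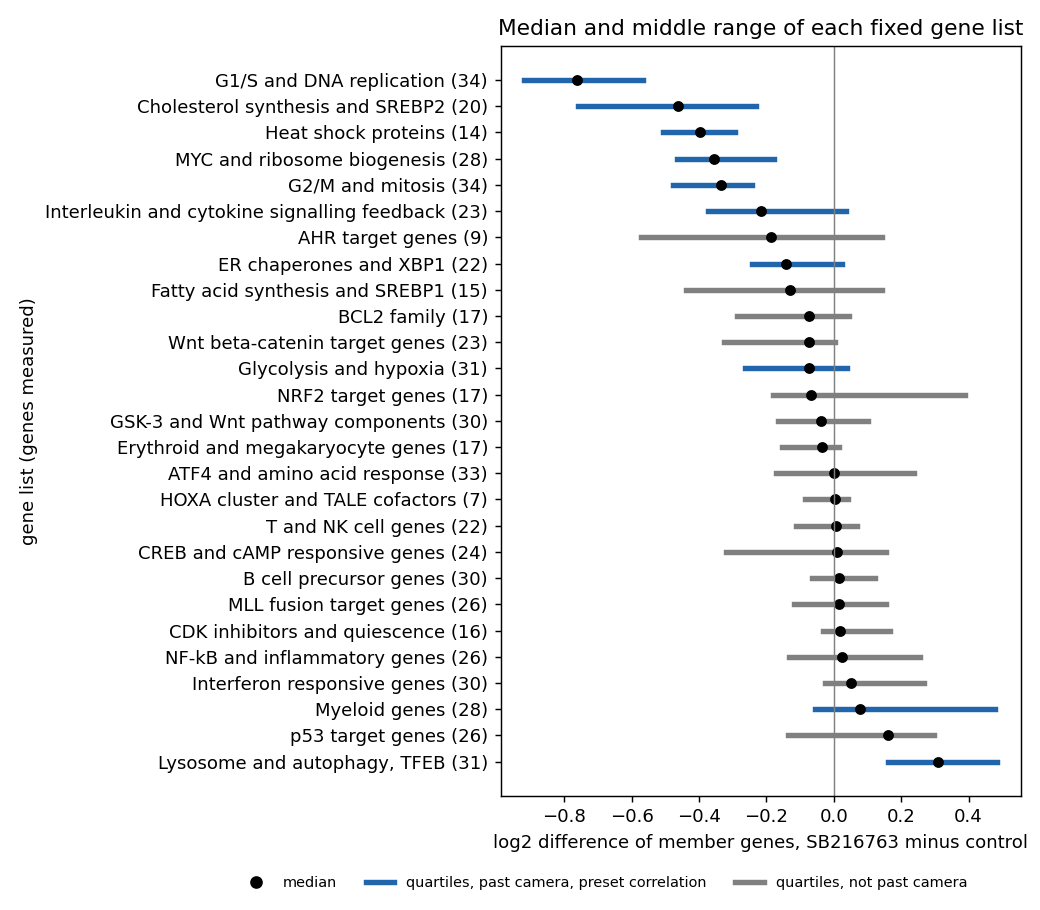
Log2 difference, SB216763 minus control, of the member genes of the 27 fixed gene lists (horizontal axis); each list is named on the vertical axis with its number of measured genes. Points are medians and bars run from the lower to the upper quartile, blue for the 10 lists past camera with the preset correlation and grey for the rest; medians run from -0.76 for DNA replication to 0.31 for the lysosome.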

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

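The signals in probes left out of the comparison were tested as laid down in advance; of the tests in this part, those for a shift of all genes, for short-lived immediate early transcripts and for the size of each change with 1 array left out were chosen after the result was seen. So were the rule that the upper quartile of the myeloid transcripts had to lie under the bound as well, and the reading of member counts without a control array as undecided. Probes outside the gene test were flagged because the comparison does not use them. With every probe tested singly by limma, 290 of 12083 unnamed probes were past the threshold and higher with SB216763 and 114 were lower, 3.34% in all. Of 1754 probes with several genes, 127 were higher and 35 lower, 9.24% in all, against 6.89% of the probes with 1 gene.

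DNA replication genes fell as a group, with 31 of 34 measured members lower and adjusted p = 0.415 with an estimated correlation. Genes outside the list had a median log2 difference of 0.0036, so on the scale of these values the fall was not shared by all genes. The deposited arrays already had similar medians, so a change in total RNA would not show here and is not excluded. A test set beforehand took dependence on 1 array to mean that fewer than 17 members would fall without it; that bound was crossed, since limma called 0 members without either control array, but the same fits called 1 and 0 of 18417 genes, so the count decides nothing about this list. The list's median stayed at -0.65 or below whichever array was left out, so no single array set the size of the fall. A hypothesis is that fewer cells were in S phase. Replication-dependent histone genes, transcribed in S phase and absent from the list, had a median of -0.31 over 50 measured genes, which would go with it. Expressed genes in this part are the brighter genes, with a mean over all arrays at or above the median of all genes. Genes above background can thus be left out. Camera was run on the 37 expressed histone genes, and they too lost their call with an estimated correlation (adjusted p = 0.103). H4C14 and H4C15 held identical values, so the histone genes are not all separate measurements.

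Lysosomal genes rose, with a list median of 0.31 and adjusted p = 0.415 with an estimated correlation. Among 10000 random lists matched on mean expression that median stood at percentile 100, so the brightness of the probes does not account for it. The number of members called fell to 0 without either control array, as it did for nearly all genes and so without deciding the matter, while the median was at least 0.26 whichever array was left out. A second lysosomal list, written before its values were seen, had a median of 0.31 over 42 expressed genes (adjusted p = 0.124 with an estimated correlation), and a rise of lysosomal genes beyond the fixed list may therefore be present. More myeloid-like cells could also give this: 15 abundant myeloid transcripts had a median of 0.044, under the bound set beforehand against that explanation. It is left open only by choices made after the values were seen. That bound was then also asked of the upper quartile, which was 0.29, and a subset of 8 expressed transcripts had a median of 0.29. This subset leaves out S100A8, S100A9, FCN1, MPO and CD14, which were above background on all arrays.

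Of 10 ERK-dependent genes of the feedback list, a subset taken after the result was seen and not tested as a set, 5 fell, with a median of -0.28 over the 10, and the whole list had adjusted p = 0.415 with an estimated correlation. Handling can lower short-lived transcripts, but 9 expressed immediate early genes had a median of -0.013 and a lower quartile of -0.22, although FOS and EGR1 fell. A fall of these genes as a set was thus not seen. Immediate early genes can also respond to ERK, so this median does not separate handling from lower ERK output. Limma called 0 of the 10 without either control array, again as for nearly all genes, and their median lay at -0.26 or further from 0 whichever array was left out. Lower output of the ERK pathway is a hypothesis that could account for it: a second list of ERK-responsive genes had a median of -0.28 over 8 expressed genes, and -0.30 over the 6 that are not among the feedback genes. Of the 8 expressed genes limma called 3 lower, and camera gave that list an adjusted p of 0.124 with an estimated correlation.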

How the results depend on the processing

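The counts were not stable. All 2418 called genes kept their direction after quantile normalization and with each array centred; leaving out 1 array could not change it, since their groups did not overlap. Among list medians and named genes not called, 9 lists and 4 genes changed sign in some setting. Only brighter genes gave 47 higher at least 2-fold. No moderation gave 126 higher and 125 lower, 23 and 23 at least 2-fold, since the spread then has few degrees of freedom. Array weights gave 2568 higher and 2152 lower; the cause was not tested. With 1 array left out, the counts ranged from 0 to 1680 higher, 0 to 1179 lower, 0 to 94 higher at least 2-fold and 0 to 61 lower at least 2-fold; the lowest came without a control array, which leaves 1 control array, and there limma had 3603 and 3960 genes at an unadjusted p under 0.05. Quantile normalization and centring left 46.7% and 45.3% of calls higher, against 54.9%, so which direction holds more genes depends on the scaling. Lists called numbered 8 to 11 across the settings of the values and the fit; camera with an estimated correlation called 0, against 15 by fry. The replicate block gave 941 higher and 889 lower; same-numbered arrays had deviations correlated at -0.05 and -0.10, with only 2 shared numbers, so the numbers are not taken to pair the arrays. Linear values plus 16 were not run, since the values are log2. Signal over background limits the 82 called genes above background on no array.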

Other observations

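The gene families and the tests against background in this part were chosen after the data were seen. Cytosolic ribosomal protein genes were higher as a group: of 59 measured, 21 rose, with a median of 0.24, among them RPL31 by 0.71 (SE 0.07), RPL28 by 0.75 (SE 0.09) and RPS27 by 0.56 (SE 0.08), and RPL39L fell by 0.45 (SE 0.10). Their median was 0.21 with each array centred and 0.17 after quantile normalization. Many have near-identical pseudogenes, so single values are uncertain. Proteasome subunit genes went the other way, with 9 of 45 lower and a median of -0.19 (-0.23 centred, -0.22 quantile), including PSMC3 by 0.50 (SE 0.09), while PSMB9, the immunoproteasome subunit, rose by 0.60 (SE 0.10). Of 482 zinc finger genes, 81 rose, with a median of 0.10 (0.06 centred, 0.07 quantile), including ZNF581 by 1.08 (SE 0.07) and ZNF117 by 1.19 (SE 0.11), and ZNF143, ZNF367, ZNF395, ZNF584 and ZNF850 fell. Camera with the preset correlation gave adjusted p-values of 1.15e-12, 6.12e-05 and 2.82e-06 for these 3 families, adjusted over 6, and adjusted p = 0.384 for each with an estimated correlation. Of the other 3 families, C/D box snoRNA genes were higher by camera (median 0.13, adjusted p = 0.00113, and 0.384 with an estimated correlation). Limma called 15 of 115 higher and 4 lower. The higher ones of smallest p were mostly numbered copies of SNORD116, while SNORD14C and SNORD14E differed by -1.19 and -1.43. SNORD116-1 and SNORD116-23 were not above background on the control arrays. Mitochondrial ribosomal protein genes were lower by camera (median -0.07, adjusted p = 0.00121, and 0.384 with an estimated correlation). H/ACA box snoRNA genes did not pass (median 0.02, or -0.01 centred; adjusted p = 0.980 with an estimated correlation). Limma called 1 gene, ALOX12, without control replicate 1 and 0 without control replicate 2 (3603 and 3960 genes at an unadjusted p under 0.05), so no family member kept its call without either, while with 1 array left out the medians ran from 0.21 to 0.30 for ribosomal protein, -0.22 to -0.16 for proteasome and 0.09 to 0.13 for zinc finger genes. They were less stable for C/D box genes, 0.08 to 0.16, and mitochondrial ribosomal protein genes, -0.13 to -0.05, and changed sign for H/ACA box genes, -0.01 to 0.07.

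The lineage lists were also set against background. Above background on both control arrays were 85.7% of the 28 measured myeloid genes (95% exact interval 67.3% to 96.0%) and 15 of the 30 B cell precursor genes (31.3% to 68.7%), which differed by Fisher's exact test, two-sided (p = 0.00513). Against 11 of the 22 T and NK cell genes and 9 of the 17 erythroid and megakaryocyte genes, Fisher's exact test of the B cell precursor genes gave p = 1 each time. On all 3 SB216763 arrays 24 myeloid and 17 B cell precursor genes were above background. Of the B cell precursor genes 12 were above background on no array, among them CD24, VPREB1, DNTT and MME, while CD37, IKZF1, IRF4, TCF3 and CD38 were above it on all 5. Of the myeloid genes 4 were above it on no array, MNDA, VCAN, CD163 and CD86, while LYZ, PRTN3, SPI1, MPO and CD14 were above it on all 5. CD24, VPREB1 and DNTT at background, beside LYZ and PRTN3 above it, run against the usual description of the line as a B cell precursor line. Other B cell precursor genes go the other way: IGLL1, PAX5 and CD79B were above background on all 5 arrays, with control means of 8.43, 6.63 and 6.61. PAX5 and CD79B lay near background, as did MPO and CD14, with control means of 6.44 and 6.35. Neither the identity of the line nor the labels were tested. These genes were named after their values were seen, and members of a list are not independent of one another.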
